A study of Mus musculus with 25 samples.

How the data were processed

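Chromatin from C3H10T1/2 cells was crosslinked, digested with MNase, sonicated and immunoprecipitated, per the labels' protocols, and libraries were sequenced. Per the submitters' processing notes reads were aligned with Bowtie 1.0.0 to the mouse genome build mm9, and deepTools was used for a step that the notes as used here do not name. The peak caller, its threshold and the sequencing depth of each library are not given in the sources used here. All coordinates are those of the files, in mm9.

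The H3K27ac files are the authors' peak lists, 1 per genotype, with 32154 peaks for H3.3WT and 33454 for H3.3G34W. Positions are in bins of 200 bp, and no list overlaps itself. For each peak the authors deposited the highest and the mean ChIP count over its bins and the mean input count, which are a signal not scaled for depth. Peak height here means the highest ChIP count per bin. The authors deposited the caller's score as −log10 values, which were infinite for 3 peaks of the H3.3WT list and 6 of the H3.3G34W list. Mappability and GC content of each peak were deposited as fractions. Heights and scores are the authors' own values and were used only to describe and rank peaks within a list; where kinds of peak from both lists were weighted alike, height entered as the rank within its own list. The columns for scaled input and log2 ratio were empty in both lists. Input was thinner in the H3.3G34W list, with a median count per bin of 1.41 against 7.20, and 37.4% against 6.94% of peaks had an input count below 0.5. Which input sample was counted for which list is not stated in the sources used here. The EZH2 file holds the positions of 4822 peaks and no height.

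The reChIP table gives 1 value per genotype for 4999 H3K36me3 regions. Its name speaks of RPKM, but the deposited values are scaled reads per region in the manner of RPM, reads scaled to a fixed library size and not divided by length. In each column every value (100%, within 1e-06 of a read) was a whole multiple of 1 step, 0.094 in H3.3WT and 0.114 in H3.3G34W, whatever the length of the region. Dividing by the step recovered whole reads. If the scale is that of RPM, the steps correspond to library totals of 10638298 and 8771930 reads, but the sources used here do not state the scale. The planned analysis took the values for RPKM. Length cancels in the ratio between libraries apart from the pseudocount, which acts on the scaled reads here. The planned pseudocount of 0.1 was kept and is worth about 1 read. How the H3K36me3 regions were called is not given in the sources used here.

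Samples were grouped by genotype and target as the labels give them. All comparisons were between single libraries, so no test across samples was possible and no p-value across regions is given. The reChIP ratio is log2 of (H3.3G34W + 0.1) over (H3.3WT + 0.1), summarised by its median with a 95% order-statistic interval. This scale understates the change of low regions. Shares have exact (Clopper-Pearson) 95% binomial intervals. Intervals of shares and of read ratios cover counting error only, and those of medians or over resampled regions and windows cover the spread within these libraries. They treat regions, peaks, windows or reads as independent draws, and amplified reads are not independent molecules. Where 1 library had 0 reads, the fold was computed against a floor of 3 reads in that library. The exact 2-sided binomial test on recovered reads, with Benjamini-Hochberg adjustment, was added after the data were examined. On simulated reads for the 4999 regions with 200 changed, it recovered 21.0% of 2-fold and 68.5% of 4-fold changes and called 3 unchanged regions in each run. The simulation held counting noise only, which the real regions exceed.

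Peaks were counted as overlapping when they shared at least 1 bp, and the counts were checked with bedtools 2.31.1. H3K27ac peaks without a partner in the other list are called WT-only or G34W-only. Chance overlap came from 1000 random circular shifts of 1 list within each chromosome. Shifts spread peaks evenly over chromosomes, so a list gathered in gene-rich chromatin exceeds them for that reason alone. H3K36me3 regions were classed by the H3K27ac peaks they overlap, and each class median was placed among 10000 random sets of regions matched on mean level in 20 bins. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

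The rule for named regions was set before the data were examined. It took the 10 largest and 10 smallest reChIP log2 ratios among regions at or above the median level, the 10 highest WT-only and G34W-only H3K27ac peaks, and the 10 widest EZH2 peaks. A few of each are described, chosen from these lists to give both directions and several chromosomes. The highest-ranked come first. No gene is named, because an mm9 gene annotation was not used here. For the same reason the planned share of H3K27ac peaks at promoters and the planned gene lists were not computed. Alternatives set before the data were examined were other pseudocounts, filters on low regions, equal column totals, autosomes only, stricter and looser overlap, stronger peaks only and joining of peaks.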

Results

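The series used chromatin immunoprecipitation and sequencing in C3H10T1/2, a mouse mesenchymal stem cell line, transduced with lentivirus to express either wild-type histone H3.3 (H3.3WT) or H3.3G34W. H3.3G34W carries a glycine-to-tryptophan substitution that is found in giant cell tumours of bone. The 25 samples fell into 21 groups by genotype and target, and 5 of them gave the values used here. These were H3K27ac in H3.3WT cells, H3K27ac in H3.3G34W cells, EZH2 in H3.3WT cells, and a sequential FLAG then H3K27me3 immunoprecipitation (reChIP) in each genotype. The other 20 samples were not analysed here. Among them were EZH2 in H3.3G34W cells, FLAG alone and a further H3K27ac sample in each genotype, and the SETD2 knockout lines. In the reChIP the tagged H3.3 was captured before the H3K27me3 antibody, so the values follow H3K27me3 on nucleosomes that carried the introduced histone. They also rise with the amount of tagged H3.3 in a region, for which no correction was made. A higher value is therefore not by itself more H3K27me3 per tagged histone. The labels give 2 reChIP samples per genotype, but the reChIP table has 1 column for each. By name and description these columns belong to the pair whose titles end in "validation", and the other pair was not analysed here. Each value thus came from 1 library per genotype. No difference therefore had a replicate check. Intervals of shares and read ratios cover counting error only, and those of medians cover the spread over regions within these libraries.

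The reChIP table asked how much H3K27me3, the repressive mark laid down by PRC2, occurred together with the introduced H3.3. Its regions were those of H3K36me3, a mark of transcribed gene bodies. The values do not show whether the mark sat on the introduced H3.3 itself. The table held 4999 H3K36me3 regions with a median length of 35.8 kb. The H3.3WT library put 146154 reads in them and the H3.3G34W library 163246 reads, a median of 15 and 19 reads per region. On the deposited scale the median region held 1.41 scaled reads in H3.3WT and 2.17 in H3.3G34W.

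FLAG-H3K27me3 was higher in the H3.3G34W library over most of the H3K36me3 regions. The median log2 ratio of H3.3G34W over H3.3WT was 0.60 (95% order-statistic interval 0.54 to 0.66), a 1.52-fold difference, with quartiles of -0.29 and 1.93. Of the 4999 regions, 3260 were higher in H3.3G34W (65.2%, exact binomial interval 63.9% to 66.5%) and 1563 were lower. The log2 ratio exceeded 1 in 2059 regions and lay below -1 in 673. On the deposited scale every chromosome had a median above 0, from 0.15 on chromosome X and 0.19 on chromosome 17 to 1.05 on chromosome 18. The size depended on the scale: with both columns set to the same total over the regions, the median log2 ratio was 0.18 and 54.6% of regions were higher in H3.3G34W. An exact binomial test on the recovered reads, which compares those 2 libraries and not the genotypes, called 1966 regions higher and 625 lower in H3.3G34W among 4823 regions with reads (Benjamini-Hochberg adjusted p below 0.05). Regions scattered far more than counting allows. Over the 1871 regions with at least 50 reads the log2 ratio had an SD across regions of 1.33, against about 0.34 from counting alone.

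**Figure D1:**
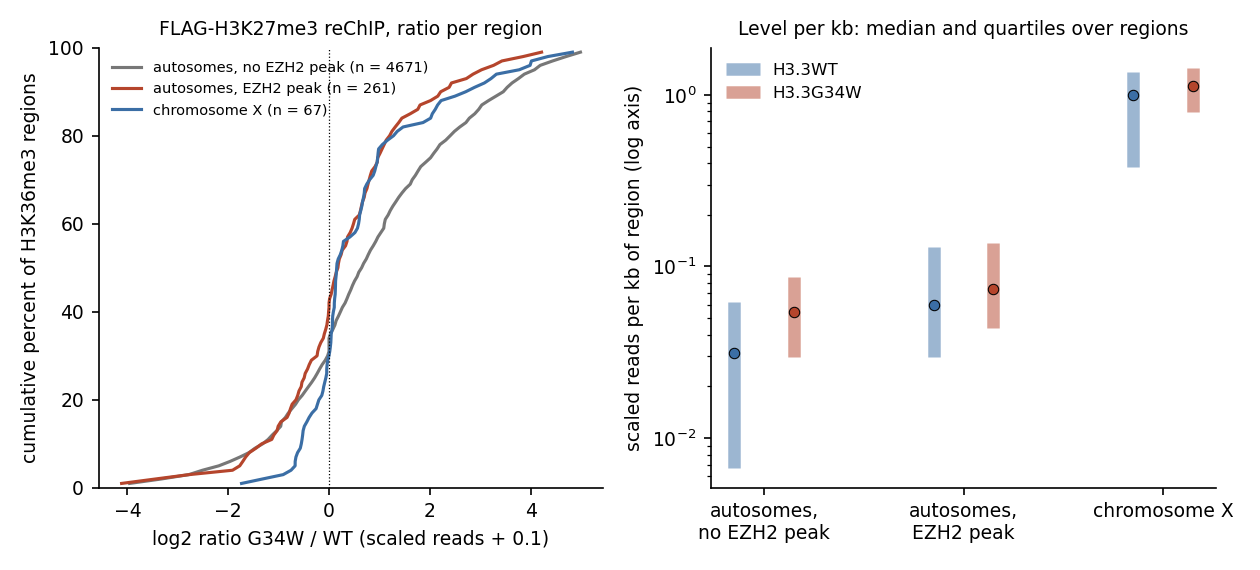
Left, cumulative percent of H3K36me3 regions (vertical axis) by log2 ratio of FLAG-H3K27me3 scaled reads, H3.3G34W over H3.3WT with 0.1 added (horizontal axis), for autosomal regions without an EZH2 peak, autosomal regions with one, and chromosome X. Right, scaled reads per kb of region on a log axis, with points at the median and bars from the lower to the upper quartile over regions: the autosomal medians without an EZH2 peak were 0.0315 in H3.3WT and 0.0540 in H3.3G34W, and those on chromosome X were 1.00 and 1.13.

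The regions with the largest ratios held no or almost no reads in 1 of the libraries. On chromosome 12, the region from 58334600 to 58353399 (mm9) had 0 reads in H3.3WT and 101 in H3.3G34W, at least 40.8-fold higher against a floor of 3 reads in the library. The region from 61538800 to 61574599 on chromosome 11 had 0 and 76 reads, at least 30.7-fold higher. On chromosome 7, the region from 109046000 to 109077399 had 1 read against 116, a 141-fold difference with a counting interval of 24.8 to 5604. In the opposite direction, the region from 155063800 to 155078199 on chromosome 2 had 48 reads in H3.3WT and 0 in H3.3G34W, at least 13.2-fold lower. On chromosome 5, the region from 125074200 to 125098399 had 71 reads in H3.3WT and 3 in H3.3G34W, 19.5-fold lower with an interval of 6.41 to 96.9. These intervals make no allowance for the choice of the most extreme regions or for scatter beyond counting. Such regions were more frequent on 1 side: 252 regions had 0 reads in H3.3WT and at least 10 in H3.3G34W, and 75 the reverse. Regions with 0 reads were more frequent in H3.3WT in general, at 728 against 337 in H3.3G34W, with 176 in both. In regions of 1.2 to 16.2 kb the median was 0.0877 reads per kb in H3.3WT and 0.444 in H3.3G34W. In longer regions it was 0.309 to 0.400 and 0.462 to 0.514. The larger number on the H3.3G34W side is therefore not by itself a sign of more regions gaining H3K27me3.

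The difference between the libraries was smaller where EZH2 was bound in H3.3WT cells. The 261 H3K36me3 regions that overlapped an EZH2 peak, EZH2 being the catalytic subunit of PRC2, had a median log2 ratio of 0.18 (interval 0.04 to 0.36). The 4738 regions without one had a median of 0.63 (interval 0.58 to 0.71). Regions with an EZH2 peak held more reads in both libraries, at medians of 3.38 scaled reads in H3.3WT and 4.22 in H3.3G34W, against 1.32 and 2.17 without. Summed over the regions, the H3.3G34W values were 1.00 times those of H3.3WT with an EZH2 peak and 1.42 times without. The median of the regions with an EZH2 peak lay at percentile 0.05 of 10000 random sets matched on mean level, and at percentile 0.01 of sets matched on length. The middle medians of those sets were 0.48 and 0.59. The difference was less clear in long regions. Among autosomal regions of at least the median length the median was 0.36 with an EZH2 peak and 0.60 without, a difference of -0.24 (interval -0.48 to 0.01 over resampled regions). With both columns set to the same total, the median at EZH2 peaks turned to -0.19. The EZH2 peaks came from H3.3WT cells, and this split was chosen after the data were examined.

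Chromosome X stood apart in level. Its 67 H3K36me3 regions held a median of 168 recovered reads in H3.3WT and 194 in H3.3G34W. Not scaled for library size, the medians were 10.6 and 9.89 reads per kb, against 0.349 and 0.481 on the autosomes. In scaled reads per kb they were 1.00 and 1.13, against 0.0328 and 0.0549. The 67 regions took 13.9% of the reads of all regions in H3.3WT and 11.6% in H3.3G34W. The median log2 ratio on chromosome X was 0.15 (interval 0.07 to 0.61), and 47 of the 67 regions were higher in H3.3G34W. With equal column totals that median turned to -0.28.

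The reChIP ratio was similar whichever class of H3K27ac peak a region held. Regions with only shared H3K27ac peaks had a median log2 ratio of 0.61 (1636 regions), regions with WT-only peaks 0.68 (1012) and regions with G34W-only peaks 0.58 (723). It was 0.52 in the 765 regions with peaks of both kinds and 0.60 in the 863 without an H3K27ac peak. The class medians lay between percentiles 10.1 and 90.3 of random sets matched on mean level, inside the central 95% for each class.

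H3K27ac, the mark of active promoters and enhancers, was compared between the peak lists of the 2 genotypes. The H3.3WT list held 32154 peaks and the H3.3G34W list 33454, a ratio of 1.04. Peaks were narrower in H3.3G34W, with a mean width of 3.83 kb against 4.50 kb. The covered length was accordingly smaller, at 128 Mb against 145 Mb, a ratio of 0.885. Peaks wider than 20 kb numbered 657 in H3.3WT and 323 in H3.3G34W. All of these broad H3.3WT peaks overlapped the H3.3G34W list, which covered a median of 78.1% of their length, and 467 of them spanned more than 1 H3.3G34W peak. Both the number and the width of peaks depend on sequencing depth and on the threshold of the peak caller, neither of which is given in the sources used here.

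Most H3K27ac peaks were present in both lists. Of the H3.3WT peaks 69.3% (22289 of 32154, interval 68.8% to 69.8%) overlapped an H3.3G34W peak by at least 1 bp. Of the H3.3G34W peaks 70.9% (23709 of 33454, interval 70.4% to 71.4%) overlapped an H3.3WT peak. Random circular shifts of the lists gave 10.5% in both directions, and none of 1000 shifts reached more than 13.5%. Peaks in 1 list only were mostly weak. WT-only peaks had a median height of 36 and a median width of 1.8 kb, against 110 and 3.6 kb for shared peaks of that list. G34W-only peaks also had a median height of 36 and a width of 1.8 kb, against 98 and 3 kb. In the lowest decile of height 77.3% of H3.3WT peaks had no partner, and in the highest decile 1.06% (34 of 3216). The same deciles of the H3.3G34W list had 75.7% and 0.209% (7 of 3346).

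**Figure D2:**
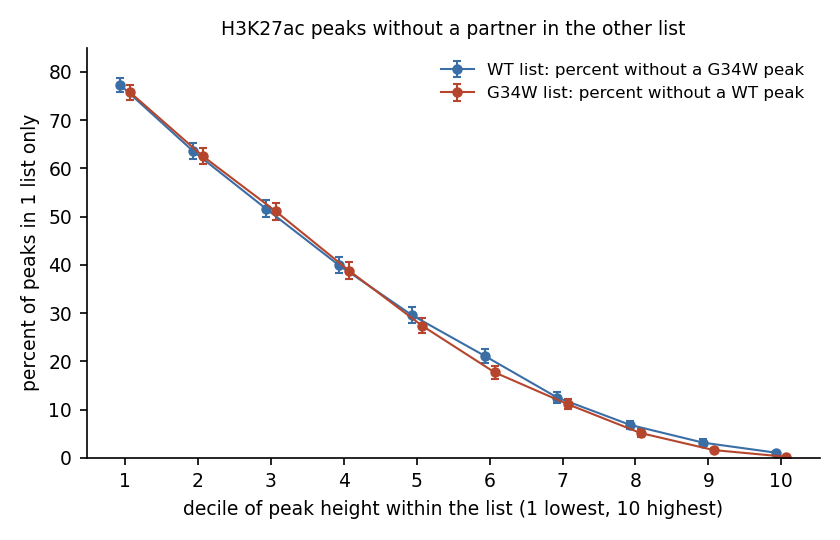
Percent of H3K27ac peaks in 1 list only (vertical axis) by decile of peak height within the list (horizontal axis), with exact binomial 95% intervals as bars. Both lists fall together, from 77.3% and 75.7% in the lowest decile to 1.06% and 0.209% in the highest.

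Among the highest WT-only peaks were 115346000 to 115353999 on chromosome 5, with a height of 544, and 58006400 to 58018399 on chromosome 11, with a height of 477. A pair of others lay close together on chromosome 5, at 121334000 to 121339599 and 121355400 to 121358599, with heights of 469 and 494 and mappabilities of 0.521 and 0.560. The highest G34W-only peak was 49306800 to 49308199 on chromosome 2, with a height of 533 in 1.4 kb. It was followed by 30340400 to 30349599 on chromosome 9, with a height of 430 over 9.2 kb, and 8644800 to 8648399 on chromosome 12, with a height of 412 and a mappability of 0.558. The fourth, 17820600 to 17829199 on chromosome 6, had a height of 411 but also a mean input count of 38.9 per bin, against a median of 1.41 over the H3.3G34W list. In the H3.3WT list 340 peaks (1.06%) were higher than the highest WT-only one, and in the H3.3G34W list 311 peaks (0.930%) were higher than the highest G34W-only one.

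**Figure D3:**
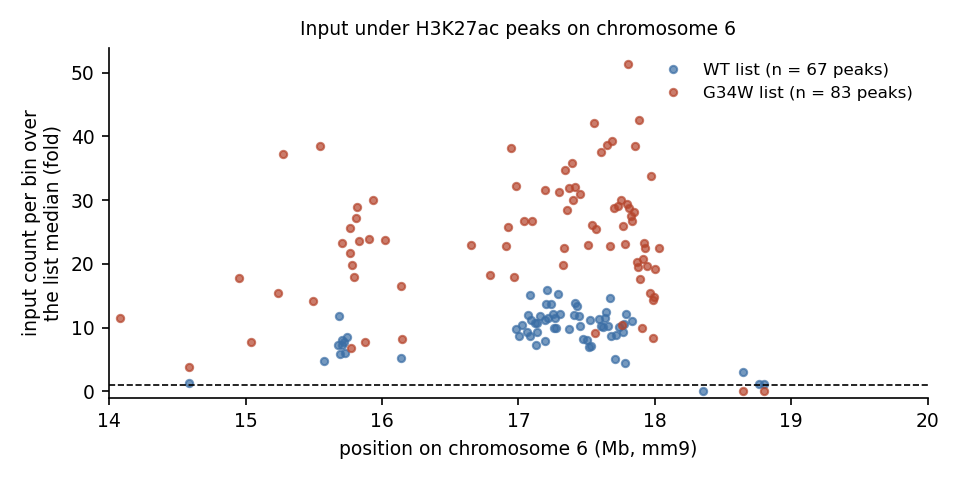
Mean input count per bin under each H3K27ac peak on chromosome 6 between 14 and 20 Mb (mm9, horizontal axis), as a fold over the median of all peaks of the same list (vertical axis, dashed line at 1). Between 17 and 18 Mb the median fold was 10.7 in the H3.3WT list and 27.2 in the H3.3G34W list.

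H3K36me3 regions held fewer of the G34W-only than of the WT-only H3K27ac peaks. Of the WT-only peaks 29.2% (2878 of 9865, interval 28.3% to 30.1%) lay in an H3K36me3 region, and of the G34W-only peaks 23.5% (2286 of 9745, interval 22.6% to 24.3%). Shared peaks were alike, at 33.7% of the H3.3WT list and 33.3% of the H3.3G34W list. H3K27ac covered 48.2 Mb of the H3K36me3 regions in H3.3WT and 39.7 Mb in H3.3G34W, a ratio of 0.824. Outside these regions the covered length was 96.7 Mb and 88.5 Mb, a ratio of 0.915. Shifted regions would hold 10.8% of the H3.3WT peaks and 10.7% of the H3.3G34W peaks. This comparison was chosen after the data were examined. Without the 900 windows of 1 Mb that held at least 10 list-specific peaks, the shares were 21.0% of 2750 and 19.5% of 2761 peaks. That gap of 1.46 points had an interval of -0.725 to 3.48 over resampled windows, which includes 0. In the 900 windows the gap was 7.33 points (interval 5.47 to 9.14).

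**Figure D4:**
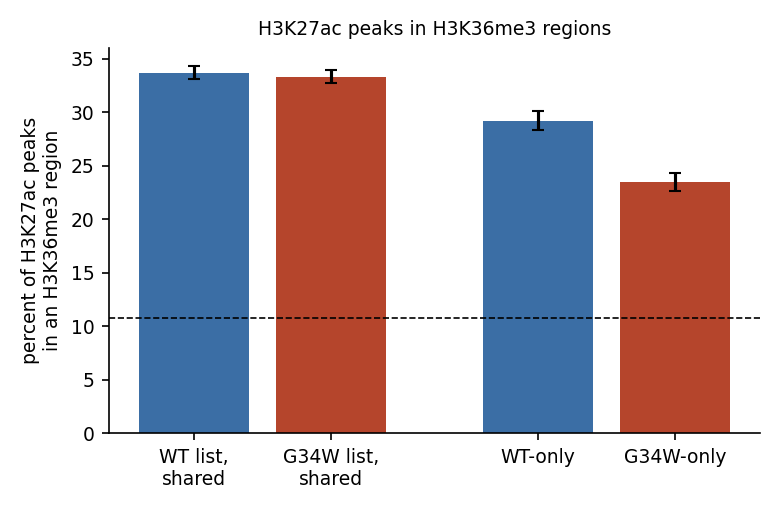
Percent of H3K27ac peaks that overlap an H3K36me3 region (vertical axis), for shared peaks of each list and for peaks in 1 list only, with exact binomial 95% intervals as bars. The dashed line marks the 10.8% that shifted regions gave for the H3.3WT list, and the G34W-only bar at 23.5% is the lowest.

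EZH2 in H3.3WT cells was compared with H3K27ac to see how often both occupied the same place. The EZH2 list held 4822 peaks that covered 16.8 Mb, with a median width of 2 kb. Of these 4069 (84.4%) overlapped no H3K27ac peak of either list. H3.3WT H3K27ac peaks overlapped 651 EZH2 peaks (13.5%, interval 12.5% to 14.5%), and H3.3G34W peaks overlapped 666 (13.8%, interval 12.8% to 14.8%). Shifts gave means of 10.5% and 9.78%, and 1 and 0 of 1000 shifts reached the observed numbers. Most of the overlapped EZH2 peaks, 564, met H3K27ac in both lists. Another 87 met it in H3.3WT only and 102 in H3.3G34W only, so that 54.0% of these 189 had the H3.3G34W peak, with an interval of 46.6% to 61.2% that includes equal shares. EZH2 peaks with H3K27ac in both lists were narrow, at a median of 1 kb against 2.2 kb for those without H3K27ac. Shared H3K27ac peaks met an EZH2 peak more often than list-specific ones, at 2.55% against 0.720% in H3.3WT and 2.41% against 0.975% in H3.3G34W. Part of this came from their greater width, since shifted EZH2 peaks gave 1.78% against 1.22% and 1.62% against 1.13%. Weighted to the widths of the list-specific peaks, a check chosen after the data were examined, shared peaks met EZH2 in 1.54% and 1.64%. The differences were then 0.818 points in H3.3WT (interval 0.547 to 1.09 over resampled windows) and 0.668 in H3.3G34W (0.398 to 0.943).

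EZH2 was rarer inside H3K36me3 regions than chance placement gave. It overlapped 261 of the 4999 regions (5.22%, interval 4.62% to 5.87%), whereas shifts gave a mean of 366 and never fewer than 300. The 10 widest EZH2 peaks included 102732200 to 102901799 on chromosome 15, at 170 kb, and 96111200 to 96209999 on chromosome 11, at 98.8 kb. Neither overlapped an H3K27ac peak of either list. The third widest, 3022200 to 3099999 on chromosome 11 (77.8 kb), overlapped 1 peak of each list. The fourth, 19917200 to 19991399 on chromosome 8 (74.2 kb), overlapped 3 of each and also 2 H3K36me3 regions. It lies in a window where the input count was 11.9-fold and 29.1-fold the list medians. On chromosome 11, 97389200 to 97444599 (55.4 kb) overlapped an H3K27ac peak in H3.3WT and none in H3.3G34W.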

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

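Apart from the setting with equal column totals, which was set beforehand, all tests in this part were chosen after the results were seen. The input counts that accompany the H3K27ac peaks reached at least 4 times the list median in both lists in 3 of the 1594 windows of 1 Mb with at least 5 peaks in each list. The other windows among the 2139 with a peak were not screened. On chromosome 6 from 15 to 16 Mb the median input was 7.35-fold the list median in the H3.3WT list and 23.2-fold in the H3.3G34W list. From 17 to 18 Mb it was 10.7-fold and 27.2-fold. On chromosome 8 from 19 to 20 Mb it was 11.9-fold and 29.1-fold. The folds are not comparable between lists, because the list medians are 7.20 and 1.41. Which input sample was counted for which list is not stated in the sources used here.

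G34W-only H3K27ac peaks gathered in clusters. The largest excess in 1 Mb was 31 peaks, on chromosome 5 from 16 to 17 Mb (32 G34W-only, 1 WT-only). The same excess was found on chromosome 6 from 17 to 18 Mb. The largest in 1000 shuffles of the 2 kinds over the genome was 26, which argues against independent placement of single peaks only. Any regional difference between the 2 lists could exceed such shuffles, so they do not tell its cause. The largest excess of WT-only peaks in 1 Mb was 28. On chromosome 6 input was raised in both lists, at 27.2-fold the median of the H3.3G34W list and 10.7-fold that of the H3.3WT list. Extra DNA copies are a candidate for the raised input. A rise in both lists does not by itself account for peaks called in 1 list only. The input may also not come from the cells of the list's genotype. Between 14 and 20 Mb, peaks with input at 4 or more times the list median spanned 15574800 to 17834199 in the H3.3WT list. In the H3.3G34W list they spanned 14080000 to 18028999. Peaks inside these spans had a median ChIP count of 0.765 (H3.3G34W) and 0.409 (H3.3WT) times the input count. The counts are not scaled for depth, and no such ratio is given here for the whole lists. For the other 9 of the 10 windows with the largest excess the larger input fold had a median of 1.63 (range 0.735 to 2.83). Input lay below the list median in both lists in 4 of the 9, so it gave no sign of extra copies in those 4. In the rest extra copies cannot be told apart from other causes while input of the H3.3G34W list is this thin. A difference between the transduced lines that is unrelated to the mutation, or an effect of H3.3G34W, may explain the clusters, and with 1 line per genotype neither was tested.

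FLAG-H3K27me3 was higher in H3.3G34W over most H3K36me3 regions and less so at EZH2 peaks. A single scale factor per library would not by itself make the gap between regions with and without an EZH2 peak. Apart from the pseudocount, such a factor cancels there by construction. The medians differed by -0.47 (interval -0.62 to -0.28 over 1000 resamples of autosomal regions). In regions of at least the median length the difference of -0.24 had an interval of -0.48 to 0.01. Random sets matched on mean level had a middle median of 0.48, so part of the gap may go with level. A single scale factor remains open for the overall level, since equal totals leave a median of 0.18 and no library total is stated. Too few H3.3WT reads in short regions were not the source of the overall level, as regions of at least the median length gave 0.59 (interval 0.52 to 0.65). More even background in the H3.3G34W library cannot be told apart from a gain of H3K27me3 on H3.3G34W nucleosomes outside H3.3WT EZH2 peaks. Regions with an EZH2 peak held 1.37 times the reads per kb of other autosomal regions in H3.3G34W and 1.89 times in H3.3WT. Both would give this. EZH2 in H3.3G34W cells and the amount of tagged H3.3 were not examined here.

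G34W-only peaks lay less often in H3K36me3 regions than WT-only peaks, by 5.72 percentage points (interval 4.16 to 7.22 over resampled windows). Weighting the peaks to the same height ranks within their lists left 6.11 points (interval 4.53 to 7.61), weighting to the same GC content left 5.66 points (interval 4.03 to 7.17), and leaving out the 20 most unequal windows left 4.70 points (interval 3.15 to 6.28). In the upper 50% of each list by height the shares were 15.7% and 10.0%, so the gap was not limited to weak peaks. Without the 900 windows that held at least 10 list-specific peaks the shares were 21.0% and 19.5%, a gap of 1.46 points whose interval of -0.725 to 3.48 includes 0, so outside these windows no gap could be told from chance. The peaks were not weighted by chromosome, although both kinds were unevenly spread. Chromosome 13 held 339 WT-only and 702 G34W-only peaks, and chromosome 12 held 598 and 280. A difference between the genotypes or between the single libraries stays open and was not tested.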

How the results depend on the processing

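No paired analysis was possible because each genotype gave 1 column or 1 list. Settings with recovered reads, region length or reads per kb were chosen after the results were seen. So were all settings for the reChIP medians at EZH2 regions and on chromosome X, and for H3K27ac shares in H3K36me3 regions. Of 97 alternative values, 52 stayed within the interval of the main value (or within 1.5-fold for numbers and ratios) and 2 changed sign. Depth limits the reChIP ratios, at a median of 15 and 19 reads per region. The settings for promoters and gene lists were not run without an mm9 annotation. Those that need a second column per genotype or FLAG columns were not run either. Joining peaks closer than 1 kb moved nothing, as no such peaks exist in the H3K27ac lists.

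With equal column totals the median reChIP log2 ratio was 0.18 and 54.6% of regions were higher. The median turned to -0.19 at EZH2 peaks and -0.28 on chromosome X, which a common factor does by construction. A pseudocount of 1 gave 0.35, and by H3K27ac class 0.29 (shared), 0.44 (WT-only), 0.39 (G34W-only), 0.41 (both kinds) and 0.29 (none). Low regions move most with it, by construction. Regions from the 25th percentile of level up gave 0.54, regions above 0 in both columns 0.51, and values per kb with a pseudocount of 0.01 gave 0.52. Recovered reads as counted gave 0.33 and 57.6%. Regions of at least the median length gave 69.3% higher, and 0.36 at EZH2 peaks, where counting EZH2 peaks within 1 kb gave 0.30. Among regions called by the exact read test 75.9% were higher. With the top 10000 peaks the WT-only class gave 0.56 (by height) and the class with both kinds 0.66 (by score).

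The shares of H3.3WT and H3.3G34W peaks overlapped by the other list were 45.8% and 44.0% with 50% reciprocal overlap, and 70.5% and 72.1% within 1 kb. They were 79.1% and 80.3% for the upper 50% of each list by height, 76.2% and 79.9% for the top 10000 by height, and 62.2% and 65.1% for the top 10000 by score. By score, the upper 50% gave 69.9% for H3.3WT. EZH2 peaks met the upper 50% of H3.3WT and H3.3G34W peaks in 11.3% and 11.3% by height and in 8.88% and 7.69% by score. They met the top 10000 in 9.60% and 9.60% by height and in 6.47% and 5.39% by score, fewer because fewer peaks were used. WT-only and G34W-only peaks in H3K36me3 regions were 15.7% and 10.0% in the upper 50% by height, 26.8% and 22.1% with the whole peak inside, and 21.0% and 19.5% without 900 crowded windows, a gap of 1.46 points with an interval of -0.725 to 3.48. The causes of the other shifts were not tested. None of the 20 named H3K27ac peaks had a partner within 1 kb.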

Other observations

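The test in this part was chosen after the results were seen. If H3.3G34W exchanged H3K27ac for H3K27me3 region by region, regions that lost H3K27ac coverage would have the higher FLAG-H3K27me3 ratio. Over 4136 H3K36me3 regions with an H3K27ac peak in either list, Spearman's rho across regions between the log2 ratio of H3K27ac coverage and the reChIP log2 ratio was 0.000696 (interval -0.0286 to 0.0325). In the fifth of the regions with the strongest loss of coverage (median log2 change -1.38) the reChIP median was 0.65, and in the fifth with the strongest gain (0.81) it was 0.74. The predicted trend was not found, although scatter between regions beyond counting would weaken one, and regions are not independent replicates. H3K27ac coverage is the length under called peaks, which depends on depth and input. It was also not limited to the tagged H3.3. The test therefore cannot decide whether tagged H3.3G34W itself exchanged the marks.

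Neighbouring H3K36me3 regions did not share their reChIP ratios: rho across 3453 adjacent pairs with at least 20 reads each was 0.03. EZH2 peaks crowded on chromosome 11, which held 513 of the 4822 peaks, 15.1% of the covered length and 21 of the 69 peaks wider than 20 kb. Chromosome 11 also held 2382 of the 32154 H3.3WT H3K27ac peaks and 408 of the 4999 H3K36me3 regions. The reason for the crowding was not tested. Chromosome X held 1.60% of the EZH2 peaks, and input under its H3K27ac peaks was 0.926 times the list median in the H3.3WT list and 0.405 times in the H3.3G34W list, while its H3K36me3 regions held 30.5 and 20.5 times the autosomal FLAG-H3K27me3 per kb. WT-only H3K27ac peaks had their own clusters, the largest on chromosome 11 from 119 to 120 Mb with 32 WT-only and 4 G34W-only peaks. Input in that window was 1.76-fold the median of the H3.3WT list and 2.15-fold that of the H3.3G34W list. By chromosome, the ratio of H3K27ac peak numbers ran from 0.843 on chromosome 12 to 1.26 on chromosome 13.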
